A study of Mus musculus with 12 samples.

How the data were processed

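RNA of sorted alveolar macrophages was measured on Agilent 8x60K mouse arrays in a single Cy3 channel. There were 12 arrays, 1 per mouse, from 4 genotypes with 3 mice each, and no sample was pooled or left unmapped. Genotype was taken from the sample titles and characteristics. The replicate numbers were not used to pair mice. The comparisons, tests, gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where the text says that a choice was made later.

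The scanner files hold an intensity per spot, which per the file headers was background-subtracted and spatially detrended within the array by Agilent Feature Extraction and was not normalized between arrays. The headers give version 10.7.3.1, while the processing notes of the submitters give version 9.1. The deposited series matrix holds log2 values for 20850 probes, and the sources do not say how they were made. Their scale was established from the values: each probe has a median of 0 over the 12 columns, and the columns matched the log2 scanner signal minus the array's 75th percentile and the probe's median with r between 0.99996 and 0.99998. Of these probes, 20802 matched a probe that is not a control. The medians of the columns were 0.09, 0.01 and 0.25 for WT replicates 1 to 3, 0.19, 0.08 and 0.19 for Bach1 KO, -0.04, -0.10 and -0.10 for Bach2 KO, and -0.25, -0.17 and -0.11 for DKO. The series matrix was used only as an alternative, because it holds fewer probes.

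The analysis used R 4.3.3, limma 3.58.1 and data.table (version 1.17.8). Processed signals were put on the log2 scale and the 75th percentile of the spots that are not controls was subtracted on each array. Spots that the scanner software marked as outliers (136 to 733 per array) were left out, and spots of one probe were averaged. A probe was kept when it was well above background on all 3 arrays of at least 1 genotype, which held for 30878 of 55681 probes. Probes were named through their accessions and the RefSeq table of assembly GRCm38.p6, which named 26413 probes by 1 gene. The other 29268 probes stayed unnamed and were tested as transcripts of their own. The probe with the highest mean stood for each gene, and at least 2 values per genotype were required. This left 23145 genes or transcripts, of which 13820 are named, and 3375 named genes had more than 1 probe. Of the 120 to 140 genes checked per comparison, at most 1 had another probe in the opposite direction.

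Each gene was fitted with a mean per genotype over all 12 arrays, with 8 residual degrees of freedom, by limma's lmFit and eBayes with a trend. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison. The comparisons were each of the 3 mutant genotypes against WT, DKO against each single mutant, and the interaction. Targeted genes were tested in a fit over every probe. A gene not well above background on any array of a group has no measured level there, so its difference is given as a bound ("at least N-fold") with its values on those arrays raised to at least the lowest level called well above background on each.

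The named genes are Bach1 and Bach2, then the 10 genes per direction (5 for DKO against each single mutant and for the interaction) with the largest log2 difference among those that passed. Outside the interaction their arrays had to show no overlap between the groups, which chance alone gives in 10% of genes with 3 against 3 arrays. They also had to be well above background on at least 2 of 3 arrays of each group compared. Up to 5 genes per direction were added by the largest bound and up to 4 members per gene list by the smallest adjusted p. Clone and predicted names were passed over, and some list members are not reported here.

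The 28 gene lists had 677 members, of which 660 are on the array and 590 passed the background filter. Lists with at least 5 members with complete values were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation. Eosinophil, erythroid and platelet, and mast cell and basophil markers had too few. Fry was run as a further test. Overlaps were set beside independent lists and beside 100 simulated draws without an effect.

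Alternatives were quantile normalization, scaling to the array median, no scaling, the series matrix, no filter on dim probes, a filter on all 12 arrays, the mean of a gene's probes, every probe on its own, eBayes without a trend and with robust, array quality weights, the 2 groups alone, a replicate block, slide as a random block, slide 1 alone, an adjusted p under 0.01, a 2-fold threshold, outlier spots kept, and leaving out each array. Chosen later were normexp with an offset of 50 on median signals, slide row as a term within slide 1, and leaving out WT replicate 3 and Bach1 KO replicate 3 together, or their replicates 2 together.

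The method was tested on 22561 simulated genes with the spread of these arrays. Log2 differences of 1, 2 and 3 were found for 1.49%, 47.8% and 84.8% of genes in Bach1 KO against WT. They were found for 10.4%, 56.7% and 86.4% in Bach2 KO against WT and for 1.49%, 13.4% and 40.9% in the interaction, with 8, 3 and 0 false calls. A simulated list of 20 genes shifted by -1 passed camera in all 6 comparisons and 0 others did. False calls for correlated lists were not tested.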

Results

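Gene expression was measured in alveolar macrophages, the resident macrophages of the lung airspaces, from female C57BL/6 mice aged 8 to 9 weeks. The cells came from lavage fluid and were sorted by flow cytometry. Mice were of 4 genotypes with 3 mice each: wild type (WT), mice without Bach1 (Bach1 KO), mice without Bach2 (Bach2 KO) and mice without both (DKO). Bach1 and Bach2 are related transcriptional repressors, and Bach1 is regulated by heme. Each mouse was hybridised to 1 single-colour Agilent array, which gave 12 arrays on 3 slides. All values are log2 signals relative to the 75th percentile of the same array. Group values are means ± SD and differences are means ± SE, with n = 3 mice per genotype. Where the size or the call of a named gene rested on 1 array, its value without that array is given.

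Between 45.2% (Bach1 KO replicate 3) and 72.4% (Bach2 KO replicate 3) of the 59305 non-control spots of an array were well above background, and no spot was saturated. The first principal component held 59.7% of the variance. It separated Bach2 KO and DKO arrays (scores from 113 to 144) from WT and Bach1 KO arrays (scores from -161 to -83.3). The second component, with 9.69% of the variance, placed DKO arrays (44.5 to 78.9) above Bach2 KO arrays (-77.7 to -43.5). WT replicate 3 stood apart on the third component, which held 7.55%, with a score of 123, and Bach1 KO replicate 3 lay on its other side at -75.9, while the other 10 arrays lay between -22.3 and 22.6. Correlations between arrays of one genotype lay between 0.940 and 0.988. Those between WT and Bach1 KO arrays lay between 0.938 and 0.981, and those between WT and Bach2 KO arrays between 0.823 and 0.919. All WT and Bach1 KO arrays and 2 Bach2 KO arrays shared slide 1, Bach2 KO replicate 3 was alone on slide 2, and the DKO arrays were on slide 3, scanned on a later day. The DKO genotype therefore could not be told apart from slide and scan day.

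**Figure D1:**
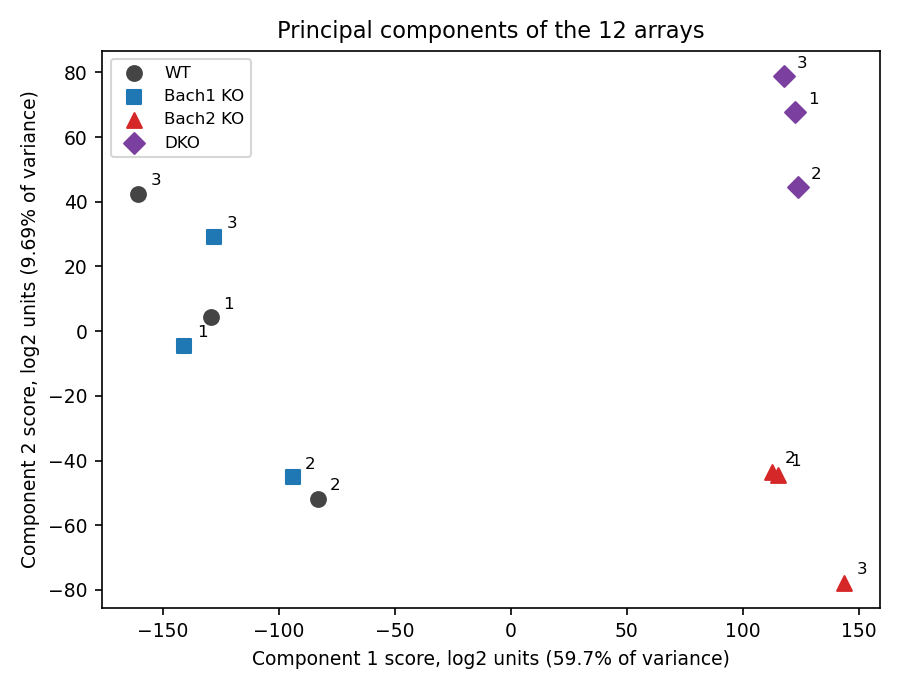
Scores of the 12 arrays on the first component (horizontal axis, log2 units) and the second component (vertical axis, log2 units) of the gene values; each point is 1 mouse, numbered by replicate, with colour and shape for genotype. Bach2 KO and DKO arrays lie at 113 to 144 on the first component and WT and Bach1 KO arrays at -161 to -83.3.

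The targeted genes were read first as a check of the labels. Bach1 had 1 probe, which was well above background on all 12 arrays. Its value was 3.93 ± 0.31 in WT, 3.94 ± 0.16 in Bach2 KO and 2.48 ± 0.71 in DKO. In the fit over all probes the difference for Bach1 KO against WT was -1.43 ± 0.32 (2.70-fold, adjusted p = 0.306), which did not pass the test. Bach1 fell in DKO against WT (-1.44 ± 0.32, adjusted p = 0.0108). In DKO against Bach2 KO its difference was -1.45 ± 0.32 (adjusted p = 0.0565), which did not pass. Bach2 had 2 probes. One was not well above background on any array. The other was well above background on 2 WT, 3 Bach1 KO, 2 Bach2 KO and 3 DKO arrays, with means of -4.24 ± 3.37, -2.90 ± 0.51, -4.77 ± 0.91 and -4.53 ± 1.19. WT replicates 1, 2 and 3 read -2.42, -2.18 and -8.13, the last not well above background. None of its differences between genotypes passed, with -0.52 ± 1.25 (adjusted p = 0.899) for Bach2 KO against WT and -1.63 ± 1.25 (adjusted p = 0.491) for DKO against Bach1 KO. The arrays therefore did not settle the Bach2 labels, and the genotypes below are those of the labels. Where the probes lie relative to the deleted parts is not given in the sources used here.

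Loss of Bach1 alone was read from Bach1 KO against WT. The MHC class II genes H2-Aa (-4.20 ± 0.51, adjusted p = 0.0122), H2-Eb1 (-4.04 ± 0.31, adjusted p = 0.000255) and H2-Ab1 (-3.27 ± 0.22, adjusted p = 9e-05) fell, as did Cd74, the invariant chain (-3.80 ± 0.49, adjusted p = 0.0145). Tnfsf14, a cytokine of the tumour necrosis factor family (3.20 ± 0.35, adjusted p = 0.00534), and Plpp3, a lipid phosphate phosphatase (3.32 ± 0.41, adjusted p = 0.0135), rose. In all, 14 of 23124 genes or transcripts tested passed an adjusted p of 0.05, 4 higher and 10 lower, and 1224 had an unadjusted p under 0.05. Of the 14, 11 have gene names. Klk8, a serine protease, fell too (-2.72 ± 0.37, adjusted p = 0.0204). Fbp1, a gluconeogenic enzyme (at least 34.3-fold, adjusted p = 4.6e-05), Btla, an inhibitory receptor (at least 7.10-fold, adjusted p = 0.0215), and Armcx2 (at least 6.32-fold, adjusted p = 0.0392) fell to a level not well above background on any Bach1 KO array. Hpse, heparanase, fell as well (-4.95 ± 0.55, adjusted p = 0.00548), with 1 of 3 Bach1 KO arrays well above background, and was chosen after its values were seen. H2-Aa was at -3.60 without Bach1 KO replicate 1. For H2-Aa, Cd74, Plpp3 and Klk8 the highest adjusted p with 1 array left out was 0.0734, 0.0822, 0.059 and 0.119, which did not pass.

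Of 15 MHC class II and antigen presentation genes, 0 rose, 4 fell and 11 did not pass, or 0 and 5 adjusted over the list alone. The list was lower by limma's camera test (adjusted p = 1.34e-06, and adjusted p = 0.114 with an estimated correlation). Of 12 dendritic cell markers, 0 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.964), with a median of -0.02. Of 30 oxidative stress, heme and iron genes, 0 rose and 0 fell, or 3 and 0 adjusted over the list alone (adjusted p = 0.176). This list did pass as higher with quantile normalization (adjusted p = 0.0143), with normexp on median signals (adjusted p = 0.0422), with the mean of a gene's probes (adjusted p = 0.0286) or with every probe on its own (adjusted p = 0.00438), and without WT replicate 3 (adjusted p = 0.0129) or Bach1 KO replicate 2 (adjusted p = 0.0153). The members past the test within the list were Gclm, a subunit of the enzyme that starts glutathione synthesis (1.51 ± 0.24, adjusted p = 0.0571), Hmox1, heme oxygenase (1.68 ± 0.33, adjusted p = 0.147), and Slc40a1, the iron exporter ferroportin (1.98 ± 0.54, adjusted p = 0.384). Cell cycle genes were lower as a list (median -0.20, adjusted p = 0.0156, and adjusted p = 0.598 with an estimated correlation), as were oxidative phosphorylation genes (median -0.26, adjusted p = 0.014, and adjusted p = 0.75 with an estimated correlation). In these lists 0 of 49 and 0 of 32 members fell on their own, also when adjusted over the list alone. The cell cycle genes did not pass with quantile normalization, with the filter on all 12 arrays, with array quality weights, with limma's fry test, with slide row as a term or without both WT replicate 3 and Bach1 KO replicate 3 (highest adjusted p = 0.759). Without WT replicate 2 (adjusted p = 0.0672), WT replicate 3 (adjusted p = 0.253) or Bach1 KO replicate 3 (adjusted p = 0.234) they did not pass either. The oxidative phosphorylation genes did not pass with quantile normalization, with the series matrix values, with limma's fry test, with slide row as a term or without both WT replicate 2 and Bach1 KO replicate 2 (highest adjusted p = 0.741). Without WT replicate 1 (adjusted p = 0.371) or Bach1 KO replicate 2 (adjusted p = 0.864) they did not pass either.

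Within slide 1 alone, 4 genes and 3 lists passed, with H2-Ab1 (adjusted p = 0.00472) and H2-Eb1 (adjusted p = 0.00762) among them and H2-Aa (-4.20 ± 0.56, adjusted p = 0.127) and Cd74 (-3.80 ± 0.49, adjusted p = 0.117) not. All WT and Bach1 KO arrays lie on slide 1, so that these differences are those given above and the estimate of the spread changed. The adjusted p there was 7.43e-06 for the MHC class II and antigen presentation genes, 0.0205 for the cell cycle genes and 0.00179 for the oxidative phosphorylation genes. With slide row as a further term, chosen after seeing the data, it was 7.34e-07, 0.438 and 0.501, so that the last lists did not pass. Slide row 1 held all WT arrays and 1 Bach1 KO array, on which the difference then rests. With slide as a random block 14 genes and 3 lists passed, at 1.36e-06, 0.0158 and 0.0133 for the same lists. The count of genes moved to 7, 86 and 23 without WT replicates 1, 2 and 3, and to 7 and 80 without Bach1 KO replicates 1 and 2. Without WT replicate 2, 66 were higher and 20 lower, and without Bach1 KO replicate 2, 15 were higher and 65 lower, against 4 and 10 over all arrays. These arrays correlated at 0.383 after genotype was removed. Without both of them 158 genes passed, 75 higher and 83 lower, and without both WT replicate 3 and Bach1 KO replicate 3 29 did, alternatives chosen after seeing the data. The median of all genes moved from -0.07 to 0.09 with no scaling, and the share of higher genes from 28.6% to 41.2%.

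**Figure D2:**
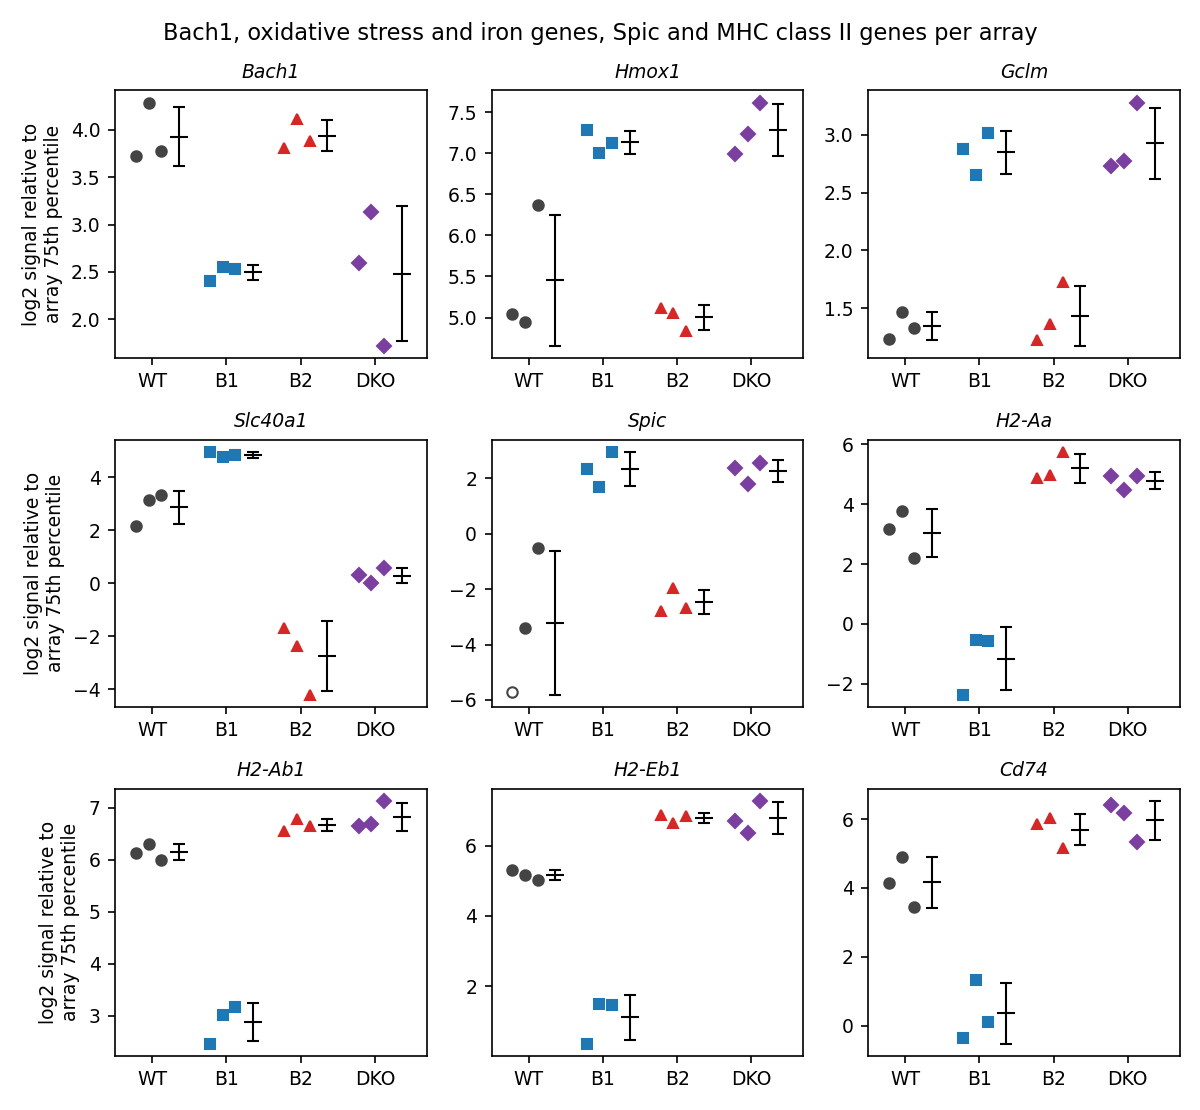
Log2 signal relative to the array's 75th percentile (vertical axis) of 9 genes in WT, Bach1 KO (B1), Bach2 KO (B2) and DKO mice (horizontal axis); filled points are arrays well above background, open points are not, and bars give mean ± SD of 3 mice. H2-Aa, H2-Ab1, H2-Eb1 and Cd74 lie lowest in Bach1 KO, and Bach1 lies lower in both genotypes without it.

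Loss of Bach2 alone was read from Bach2 KO against WT. Csf1, the macrophage colony-stimulating factor (9.67 ± 0.77, adjusted p = 4.53e-06), Pdgfa, a platelet-derived growth factor chain (9.60 ± 0.62, adjusted p = 9.48e-07), Inhba, the subunit of activin A (9.47 ± 1.74, adjusted p = 0.00175), and Mmp12, macrophage elastase (9.17 ± 0.51, adjusted p = 3.79e-07), rose. Fabp1, a fatty acid binding protein (-8.88 ± 0.62, adjusted p = 1.76e-06), and Cidec, a lipid droplet protein (-8.37 ± 0.66, adjusted p = 4.12e-06), fell. In all, 8571 of 23125 genes or transcripts passed, 2868 higher and 5703 lower, and 7328 of them differed at least 2-fold. Pdgfa was at 8.94 without WT replicate 1 and Csf1 at 8.46 and Inhba at 7.43 without WT replicate 3.

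Further large rises were those of C1qc, a chain of complement C1q (8.78 ± 0.96, adjusted p = 5e-05), Bex1 (8.77 ± 0.58), Pla2g2d, a secreted phospholipase (8.66 ± 0.41), Prnp, the prion protein (8.63 ± 1.52, adjusted p = 0.00137), Papss2 (8.59 ± 0.47) and Kcnn4, a potassium channel (8.54 ± 0.54). The 10 largest rises were picked among genes well above background on at least 2 of 3 arrays of both groups, and all of these genes but Pla2g2d and Papss2 were so on 2 of 3 WT arrays. Genes not well above background on any WT array rose to a bound: the chemokine genes Ccl24 (at least 4454-fold, adjusted p = 8.59e-10) and Ccl7 (at least 1297-fold), Retnla, a marker of alternative activation (at least 2524-fold), the growth factor gene Hbegf (at least 633-fold) and Oit3 (at least 591-fold). Apoc1, an apolipoprotein (-8.35 ± 0.47), Acot1, an acyl-CoA thioesterase (-8.10 ± 0.32, adjusted p = 4.69e-08), Grb7, an adaptor protein (-7.97 ± 0.40), and Adam22 (-7.63 ± 0.45) fell. So did Klk8 (-7.50 ± 0.37), the serotonin transporter gene Slc6a4 (-7.23 ± 0.50), the neuropeptide gene Gal (-7.16 ± 0.34) and Patj (-7.06 ± 0.38). Apoc1, Grb7, Adam22 and Patj were well above background on 2 of 3 Bach2 KO arrays. The largest falls to a bound were those of Hspa12a (at least 139.6-fold), Sobp (at least 122-fold), the integrin gene Itgad (at least 113-fold), the receptor gene Adgrg1 (at least 113-fold) and Dnah11 (at least 90.0-fold). Prnp was at 6.67 without WT replicate 1, Bex1 at 8.05 and Apoc1 at -8.97 without WT replicate 2 and C1qc at 7.38 without WT replicate 3.

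Of 33 alveolar macrophage identity genes, 2 rose, 24 fell and 7 did not pass, also when adjusted over the list alone. The identity list was lower (adjusted p = 2.29e-06, or 0.098 with an estimated correlation). Members that fell included Siglecf, a surface lectin used to identify these cells (-6.33 ± 0.47, adjusted p = 2.69e-06), Il18 (-5.80 ± 0.27, adjusted p = 1.39e-07) and Krt79 (-5.47 ± 0.29, adjusted p = 2.76e-07). Of 23 PPARgamma target and fatty acid genes, 2 rose, 11 fell and 10 did not pass, or 3 and 13 adjusted over the list alone. Acot1, Cidec and Angptl4 (-2.69 ± 0.34, adjusted p = 0.000132) fell, while Cd36, a fatty acid and lipid receptor, rose (2.51 ± 0.22, adjusted p = 9.16e-06). The list was lower (adjusted p = 0.0349, and adjusted p = 0.372 with an estimated correlation), but its median of -0.70 turned to 0.01 with quantile normalization. The PPARgamma target and fatty acid genes did not pass with quantile normalization, with no scaling, with the series matrix values, with normexp on median signals, with the filter on all 12 arrays, without a trend in eBayes or without both WT replicate 2 and Bach1 KO replicate 2 (highest adjusted p = 0.754). Without WT replicate 1 (adjusted p = 0.0554) or WT replicate 2 (adjusted p = 0.12) they did not pass either. Of 32 oxidative phosphorylation genes, 0 rose, 18 fell and 14 did not pass, or 1 and 20 adjusted over the list alone, with Ndufb8 lower (-1.71 ± 0.32, adjusted p = 0.00199). That list was lower (adjusted p = 0.00107, and adjusted p = 0.548 with an estimated correlation), and its median of -0.91 turned to 0.04 with quantile normalization, where the oxidative phosphorylation genes did not pass (adjusted p = 0.593).

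Of 49 cell cycle genes, 1 rose, 45 fell and 3 did not pass, also when adjusted over the list alone. Tk1, thymidine kinase (-4.14 ± 0.40, adjusted p = 2.12e-05), and Cdk1 (-2.26 ± 0.25, adjusted p = 6.2e-05) fell. The cell cycle list was lower (adjusted p = 4.38e-12, and adjusted p = 0.0226 with an estimated correlation). Of 21 alternative activation genes, 15 rose, 1 fell and 5 did not pass, or 15 and 2 adjusted over the list alone. Pdcd1lg2, the ligand PD-L2, rose (3.37 ± 0.23, adjusted p = 1.38e-06), as did Ccl24 and Retnla. The list was higher (adjusted p = 5.25e-10, and adjusted p = 0.00225 with an estimated correlation). Of 22 chemokine and chemokine receptor genes, 13 rose, 4 fell and 5 did not pass, or 14 and 4 adjusted over the list alone. Ccl8 (6.89 ± 0.44, adjusted p = 8.8e-07) and Ccl9 (2.43 ± 0.23, adjusted p = 1.96e-05) rose. The chemokine list was higher (adjusted p = 3.5e-07, and adjusted p = 0.0039 with an estimated correlation). Of 29 monocyte and recruited macrophage genes, 15 rose, 6 fell and 8 did not pass, or 16 and 6 adjusted over the list alone. F13a1, a coagulation factor chain, rose (at least 186-fold, adjusted p = 6.53e-07). Cd300e fell (-8.08 ± 0.58, adjusted p = 2.19e-06) with 1 of 3 Bach2 KO arrays well above background. The monocyte list was higher (adjusted p = 0.000544, or 0.017 with an estimated correlation). Cd300e was at -7.49 without Bach2 KO replicate 1.

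Of 24 matrix remodelling genes, 13 rose, 3 fell and 8 did not pass, or 13 and 4 adjusted over the list alone. Timp1, a metalloproteinase inhibitor (5.09 ± 0.31, adjusted p = 6.78e-07), Thbs1, thrombospondin (at least 277-fold, adjusted p = 2.19e-07), and Mmp13, a collagenase (at least 171-fold, adjusted p = 5.3e-07), rose. The matrix list was higher (adjusted p = 8.01e-07, and adjusted p = 0.01 with an estimated correlation). Of 31 inflammatory cytokine and NF-kB genes, 14 rose, 4 fell and 13 did not pass, or 17 and 4 adjusted over the list alone. Cxcl3 (4.39 ± 0.33, adjusted p = 3.16e-06) and Traf1 (4.89 ± 0.64, adjusted p = 0.000182) rose. The inflammatory list was higher (adjusted p = 0.000401, and adjusted p = 0.0145 with an estimated correlation). Of 24 unfolded protein response genes, 10 rose, 4 fell and 10 did not pass, or 12 and 5 adjusted over the list alone. Asns, asparagine synthetase (4.58 ± 0.35, adjusted p = 3.17e-06), and Trib3 (2.88 ± 0.40, adjusted p = 0.000297) rose. The unfolded protein response list was higher (adjusted p = 0.00295, and adjusted p = 0.098 with an estimated correlation). Traf1 was at 4.24 without WT replicate 2.

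Of 30 oxidative stress, heme and iron genes, 3 rose, 11 fell and 16 did not pass, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.33). Slc40a1 fell (-5.62 ± 0.54, adjusted p = 1.91e-05), and Slc7a11, the cystine transporter, rose (3.84 ± 0.38, adjusted p = 2.55e-05). Of 15 MHC class II and antigen presentation genes, 6 rose, 5 fell and 4 did not pass, also when adjusted over the list alone. H2-Eb1 rose (1.63 ± 0.31, adjusted p = 0.00237), H2-DMa fell (-1.87 ± 0.31, adjusted p = 0.000837), and the list did not pass (adjusted p = 0.197). Of 36 interferon-stimulated genes, 11 rose and 6 fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.0578). It passed as higher with quantile normalization (adjusted p = 0.0162), no scaling (adjusted p = 0.0435), normexp on median signals (adjusted p = 0.0112) and the series matrix values (adjusted p = 0.0393), among other settings. It passed as well without WT replicate 3 (adjusted p = 0.0064), Bach1 KO replicates 1 (adjusted p = 0.0403) and 2 (adjusted p = 0.0476) or Bach2 KO replicate 3 (adjusted p = 0.0491). The lists of surfactant lipid uptake and efflux (7 of 27 rose, 11 fell, also when adjusted over the list alone, adjusted p = 0.448), cholesterol synthesis (4 of 25 rose, 6 fell, also when adjusted over the list alone, adjusted p = 0.615), lysosome (4 of 38 rose, 11 fell, also when adjusted over the list alone, adjusted p = 0.851) and glycolysis and hypoxia genes (5 of 23 rose, 6 fell, or 5 and 8 adjusted over the list alone, adjusted p = 0.615) did not pass. With quantile normalization the lysosome genes (adjusted p = 9.41e-07) and the glycolysis and hypoxia genes (adjusted p = 0.00266) passed as higher. Slc40a1 was at -4.90 without Bach2 KO replicate 3.

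Some marker lists of other cell types were higher. Of 17 T cell markers, 11 rose, 1 fell and 5 did not pass, also when adjusted over the list alone. Il7r (11.63 ± 0.95, adjusted p = 5.48e-06, with 1 of 3 WT arrays well above background), Lck (3.62 ± 0.40, adjusted p = 5.6e-05) and Icos (5.37 ± 0.58, adjusted p = 4.77e-05, with 2 of 3) rose. The list was higher (adjusted p = 8.01e-07, or 0.0674 with an estimated correlation), and 6 of its members were well above background on all WT arrays. Of 12 dendritic cell markers tested, 6 rose, 2 fell and 4 did not pass, also when adjusted over the list alone. Cd209a (at least 146-fold, adjusted p = 1.22e-06), Flt3 (5.02 ± 0.49, adjusted p = 2.28e-05) and Ccr7, a chemokine receptor (7.21 ± 0.84, adjusted p = 8.12e-05), rose. The dendritic cell list was higher (adjusted p = 0.00395, or 0.0674 with an estimated correlation). Of its 14 members 3 stand in another list, and 10 were well above background on all WT arrays. Of 8 endothelial and fibroblast markers, 3 rose, 0 fell and 5 did not pass, also when adjusted over the list alone. The endothelial and fibroblast list was higher (adjusted p = 0.00732, or 0.098 with an estimated correlation). The members that rose were Cdh5 (at least 10.3-fold, adjusted p = 5.48e-06), Pecam1 (1.37 ± 0.45, adjusted p = 0.0344) and Lum (at least 1.44-fold, adjusted p = 0.0126), and Lum turned to -0.05 with normexp on median signals. With the filter on all 12 arrays, T cell markers (adjusted p = 0.336) and dendritic cell markers (adjusted p = 0.126) did not pass. Il7r was at 12.78 without WT replicate 2 and Ccr7 at 6.11 without WT replicate 3. For Pecam1 the highest adjusted p with 1 array left out was 0.127, which did not pass.

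Neutrophil markers (2 of 12 rose, 3 fell, or 3 and 3 adjusted over the list alone, adjusted p = 0.651) and B cell and plasma cell markers (2 of 8 rose, 1 fell, also when adjusted over the list alone, adjusted p = 0.165) did not pass as lists, the latter passing as higher without the filter on dim probes (adjusted p = 0.0426). Nor did NK cell markers (1 of 5 rose, 1 fell, also when adjusted over the list alone, adjusted p = 0.543) and lung epithelial markers (1 of 16 rose, 5 fell, or 1 and 6 adjusted over the list alone, adjusted p = 0.33). Eosinophil markers (0 of 2 rose, 1 fell, also when adjusted over the list alone), erythroid and platelet markers (1 of 5 rose, 1 fell, also when adjusted over the list alone) and mast cell and basophil markers (2 of 4 rose, 0 fell, also when adjusted over the list alone) had too few complete members for a list test. Immediate early and handling stress genes did not pass as a list (4 of 19 rose, 4 fell, or 4 and 7 adjusted over the list alone, adjusted p = 0.851).

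Within slide 1, which held 3 WT and 2 Bach2 KO arrays, 4929 genes and 13 lists passed, with Csf1 at 9.84 ± 1.02 (adjusted p = 0.000541), Inhba at 9.43 ± 2.29 (adjusted p = 0.0234) and Fabp1 at -8.34 ± 0.39 (adjusted p = 1.63e-05). The adjusted p there was 4.29e-10 for alternative activation genes, 2.18e-07 for alveolar macrophage identity genes, 2.64e-13 for cell cycle genes, 2.18e-07 for T cell markers and 0.00747 for PPARgamma target and fatty acid genes. With slide as a random block 8485 genes and 13 lists passed, and with slide row as a further term within slide 1, chosen after seeing the data, 519 genes and 13 lists. That row effect is set by the Bach1 KO arrays alone. With it Csf1 was at 9.45 ± 1.80 (adjusted p = 0.0464), Fabp1 at -8.29 ± 0.69 (adjusted p = 0.00327) and Inhba at 3.86 ± 3.13, while the measured genes named above that did not pass were, with their adjusted p, Inhba (0.639), C1qc (0.144), Prnp (0.108), Ndufb8 (0.36), Cdk1 (0.115), Traf1 (0.197), Trib3 (0.0693), Slc7a11 (0.0657), H2-Eb1 (0.638), H2-DMa (0.0982), Il7r (0.0567), Lck (0.0756), Ccr7 (0.136) and Pecam1 (0.389). The median of all genes was -0.30, and -0.53, -0.15 and 0.39 with median scaling, quantile normalization and no scaling. The share of higher genes was 33.5%, against 44.7% with quantile normalization and 68.8% with no scaling.

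**Figure D3:**
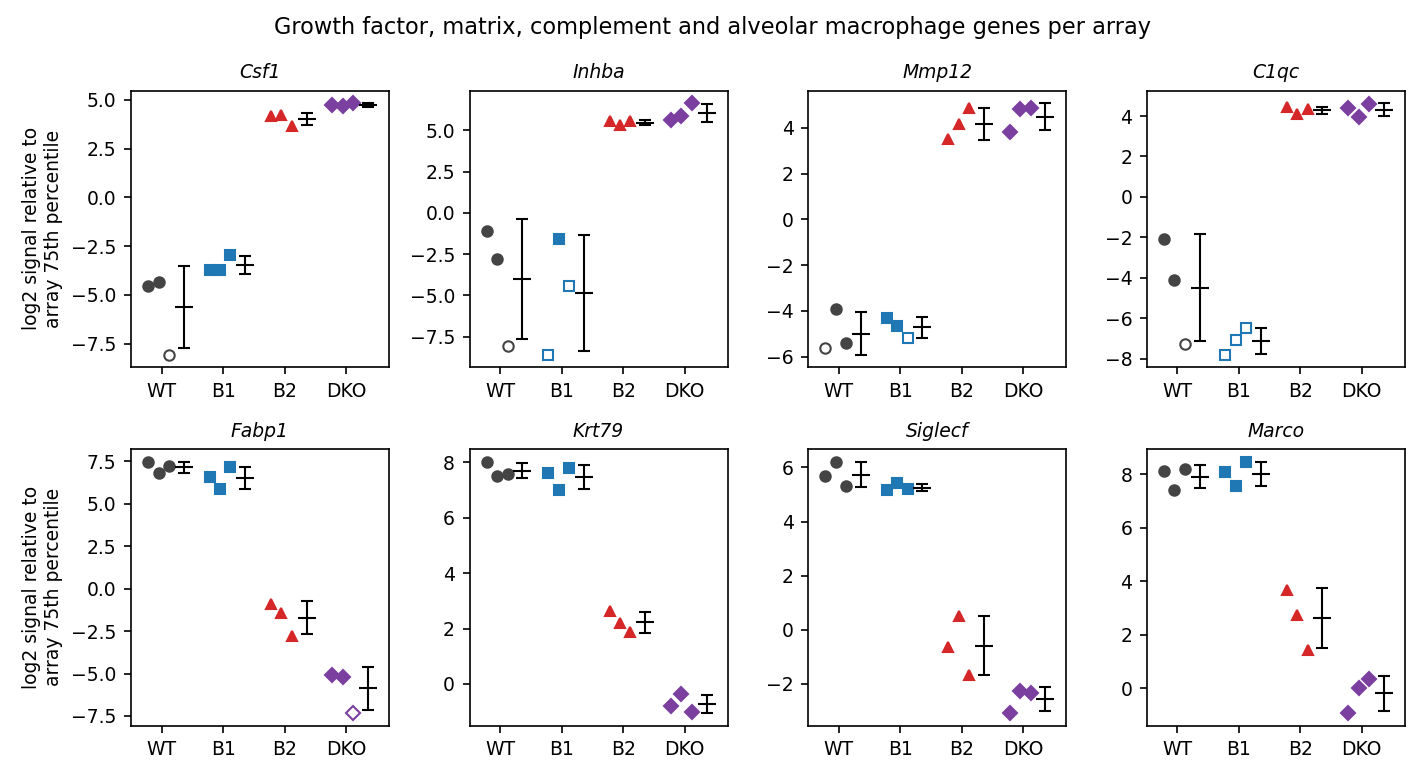
Log2 signal relative to the array's 75th percentile (vertical axis) of 8 genes in WT, Bach1 KO (B1), Bach2 KO (B2) and DKO mice (horizontal axis); filled points are arrays well above background, open points are not, and bars give mean ± SD of 3 mice. Csf1, Inhba, Mmp12 and C1qc have higher means, and Fabp1, Krt79, Siglecf and Marco lower means, in Bach2 KO and DKO than in WT.

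Loss of both genes was read from DKO against WT. Pdgfa (11.22 ± 0.62, adjusted p = 1.88e-07), Csf1 (10.38 ± 0.77, adjusted p = 1.69e-06), Inhba (10.04 ± 1.74, adjusted p = 0.00125) and Ccl2, a monocyte chemokine (9.02 ± 1.19, adjusted p = 0.000176), rose. Fabp1 (-13.02 ± 0.62, adjusted p = 8.13e-08), Alox5, the lipoxygenase of leukotriene synthesis (-9.19 ± 0.31, adjusted p = 1.02e-08), Siglecf (-8.29 ± 0.47, adjusted p = 2.19e-07) and Marco, a scavenger receptor (-8.10 ± 0.51, adjusted p = 5.36e-07), fell. In all, 6285 of 23128 genes or transcripts passed, 2443 higher and 3842 lower, and 5538 differed at least 2-fold. Fabp1 was at -12.29 without DKO replicate 3, Pdgfa at 10.56 without WT replicate 1, Ccl2 at 9.90 without WT replicate 2 and Csf1 at 9.17 and Inhba at 8.00 without WT replicate 3.

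The other large rises were those of Mmp12 (9.49 ± 0.51, adjusted p = 1.71e-07), Car6, a carbonic anhydrase (9.49 ± 0.68), Kcnn4 (8.94 ± 0.54), Ccl8 (8.83 ± 0.44), C1qc (8.80 ± 0.96) and Prnp (8.58 ± 1.52, adjusted p = 0.00148). Rises to a bound were those of Ccl24 (at least 4580-fold, adjusted p = 8.31e-10), Ccl7 (at least 3587-fold), Hbegf (at least 1597-fold), Retnla (at least 753-fold) and Mmp13 (at least 735-fold). Perp (-10.10 ± 0.65), the heme transporter family gene Flvcr2 (-9.56 ± 0.46), Lipf (-9.01 ± 0.28), the carboxylesterase gene Ces2c (-8.56 ± 0.47), Fpr1, the formyl peptide receptor (-8.51 ± 0.29), and Krt79 (-8.42 ± 0.29, adjusted p = 1.02e-08) fell. Pdgfa, Csf1, Inhba, Mmp12, Kcnn4, C1qc and Prnp were well above background on 2 of 3 WT arrays, and Fabp1, Perp, Lipf and Ces2c on 2 of 3 DKO arrays. Wfdc10 (at least 2341-fold), Spag11b (at least 1055-fold), Grb7 (at least 429.8-fold), Rufy4 (at least 381-fold) and Cracd (at least 361-fold) fell to a level not well above background on any DKO array. Perp was at -9.12 without DKO replicate 3, Prnp at 6.62 without WT replicate 1 and C1qc at 7.40 without WT replicate 3.

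Of 49 cell cycle genes, 0 rose, 45 fell and 4 did not pass, or 0 and 46 adjusted over the list alone. The cyclin genes Ccnb2 (-6.20 ± 0.29, adjusted p = 6.83e-08) and Ccna2 (-5.56 ± 0.23, adjusted p = 3.42e-08) fell. As a list they were lower (median -4.03, or -3.51 with members at their bounds, adjusted p = 4.86e-27, and adjusted p = 0.0039 with an estimated correlation). Of 33 alveolar macrophage identity genes, 3 rose, 21 fell and 9 did not pass, or 4 and 22 adjusted over the list alone. Plet1 (-7.25 ± 0.34, adjusted p = 6.83e-08) and Axl, a receptor for apoptotic cells (-5.03 ± 0.20, adjusted p = 2.35e-08), fell. The identity list was lower (adjusted p = 5.55e-09, and adjusted p = 0.0567 with an estimated correlation). Of 23 PPARgamma target and fatty acid genes, 2 rose, 10 fell and 11 did not pass, or 2 and 11 adjusted over the list alone. Lpl, lipoprotein lipase, fell (-3.52 ± 0.27, adjusted p = 2.34e-06). The fatty acid list was lower (adjusted p = 0.00111, and adjusted p = 0.146 with an estimated correlation). Of 32 oxidative phosphorylation genes, 0 rose, 9 fell and 23 did not pass, or 0 and 11 adjusted over the list alone, and the list was lower (adjusted p = 0.00411, and adjusted p = 0.516 with an estimated correlation). Oxidative phosphorylation genes did not pass with quantile normalization or with the series matrix values (highest adjusted p = 0.619).

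Of 21 alternative activation genes, 13 rose, 0 fell and 8 did not pass, or 15 and 1 adjusted over the list alone. Socs1 rose (5.01 ± 0.33, adjusted p = 6.84e-07). The activation list was higher (adjusted p = 9.56e-10, and adjusted p = 0.00247 with an estimated correlation). Chemokine and chemokine receptor genes (15 of 22 rose, 2 fell, or 16 and 2 adjusted over the list alone) were higher (adjusted p = 4.45e-08, and adjusted p = 0.0027 with an estimated correlation). Matrix remodelling genes (12 of 24 rose, 2 fell, or 13 and 2 adjusted over the list alone) were higher (adjusted p = 9.81e-08, and adjusted p = 0.00505 with an estimated correlation), with Timp1 among them (6.12 ± 0.31, adjusted p = 1.11e-07). Monocyte and recruited macrophage genes (16 of 29 rose, 4 fell, or 17 and 4 adjusted over the list alone) were higher (adjusted p = 2.89e-05, and adjusted p = 0.00608 with an estimated correlation). Inflammatory cytokine and NF-kB genes (10 of 31 rose, 4 fell, or 11 and 4 adjusted over the list alone) were higher (adjusted p = 0.00208, and adjusted p = 0.0219 with an estimated correlation). So were unfolded protein response genes (9 of 24 rose, 2 fell, or 10 and 3 adjusted over the list alone, adjusted p = 0.00174, and adjusted p = 0.0959 with an estimated correlation). Interferon-stimulated genes (11 of 36 rose, 3 fell, also when adjusted over the list alone) were higher (adjusted p = 0.0106, and adjusted p = 0.243 with an estimated correlation), with Usp18 among them (6.17 ± 0.63, adjusted p = 2.17e-05). Usp18 was at 7.10 without WT replicate 3.

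Of 30 oxidative stress, heme and iron genes, 5 rose, 8 fell and 17 did not pass, or 5 and 10 adjusted over the list alone, and the list did not pass (adjusted p = 0.683). Gclm (1.58 ± 0.24, adjusted p = 0.000437), Hmox1 (1.83 ± 0.33, adjusted p = 0.00166) and Slc7a11 (3.58 ± 0.38, adjusted p = 3.22e-05) rose, and Nqo1, a quinone reductase, fell (-3.39 ± 0.42, adjusted p = 0.000112). T cell markers were higher as a list (11 of 17 rose, 0 fell, also when adjusted over the list alone, adjusted p = 7.27e-08, and adjusted p = 0.0554 with an estimated correlation), with Lck among them (4.50 ± 0.40, adjusted p = 7.36e-06). Dendritic cell markers (6 of 12 rose, 1 fell, also when adjusted over the list alone, adjusted p = 0.0169, and adjusted p = 0.1 with an estimated correlation) and endothelial and fibroblast markers (4 of 8 rose, 0 fell, also when adjusted over the list alone, adjusted p = 0.0246, and adjusted p = 0.157 with an estimated correlation) were higher, with Flt3 among the former (4.30 ± 0.49, adjusted p = 5.77e-05). T cell markers did not pass with the filter on all 12 arrays (adjusted p = 0.161), and dendritic cell markers with the filter on all 12 arrays or without both WT replicate 2 and Bach1 KO replicate 2 (highest adjusted p = 0.301). Endothelial and fibroblast markers did not pass with normexp on median signals or without both WT replicate 2 and Bach1 KO replicate 2 (highest adjusted p = 0.105). Without WT replicate 1 (adjusted p = 0.052), WT replicate 2 (adjusted p = 0.0661) or DKO replicate 1 (adjusted p = 0.051) they did not pass either. With no scaling, 62.9% of the genes that passed were higher, against 38.9% here, and the median of all genes moved from -0.28 to 0.16. Flt3 was at 3.68 without DKO replicate 1.

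**Figure D4:**
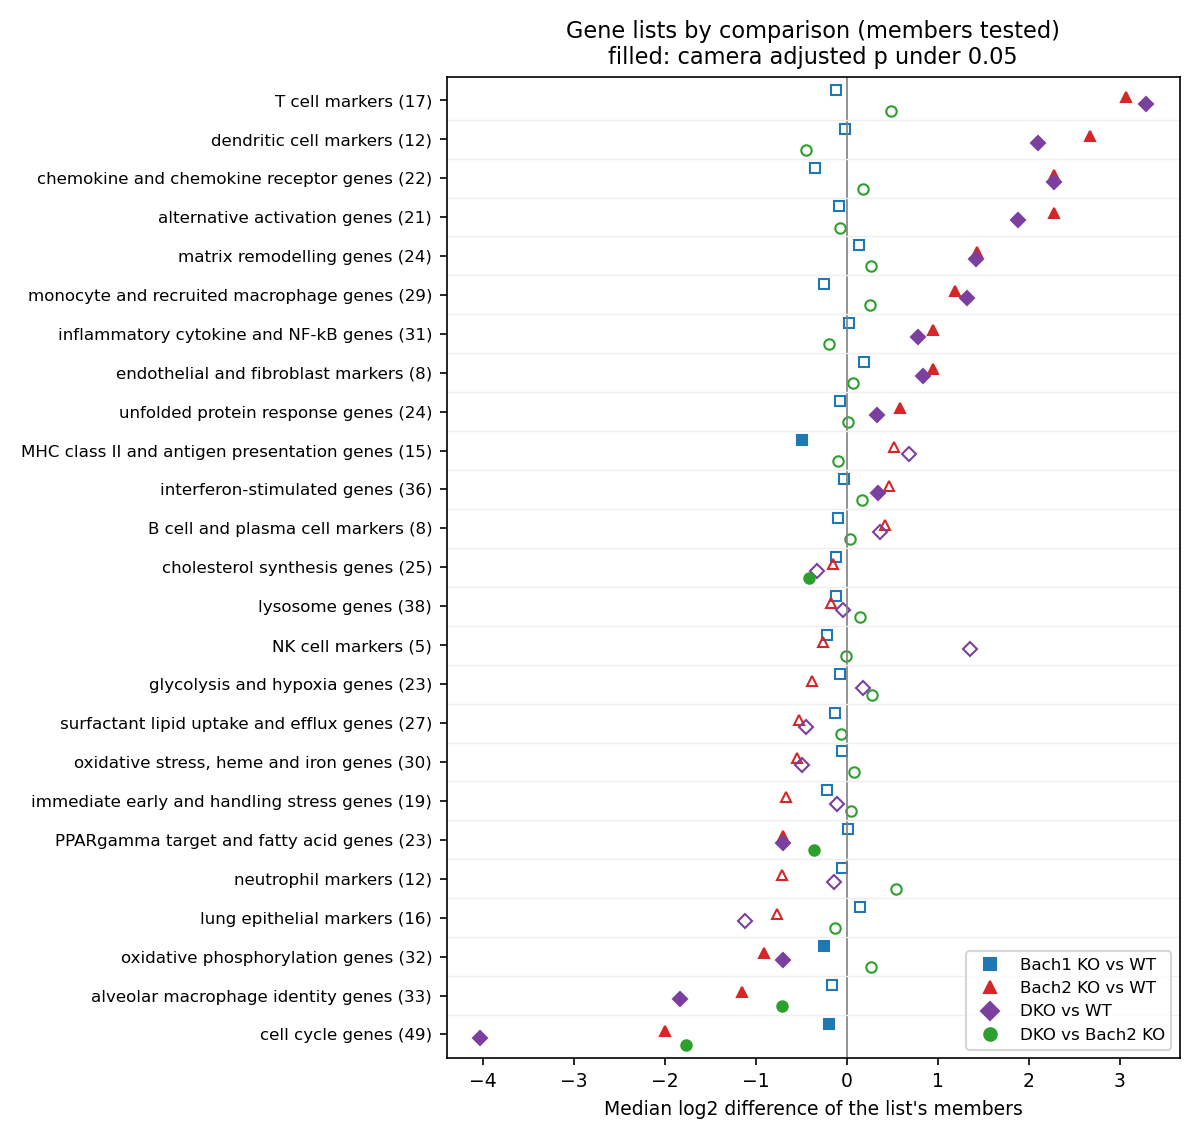
Median log2 difference of the members of each of 25 gene lists (horizontal axis, log2 units) for 4 comparisons (colour and shape), with list names on the vertical axis; filled points have a camera adjusted p under 0.05. Cell cycle genes lie lowest in DKO against WT, and with quantile normalization the Bach2 KO medians of the PPARgamma and oxidative phosphorylation lists turned to 0.01 and 0.04.

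Loss of Bach1 where Bach2 was absent was read from DKO against Bach2 KO. Hmox1 (2.28 ± 0.33, adjusted p = 0.00332), Gclm (1.49 ± 0.24, adjusted p = 0.00585), Slc40a1 (3.04 ± 0.54, adjusted p = 0.011) and Spic, a transcription factor of iron-recycling macrophages (4.72 ± 0.95, adjusted p = 0.0222), rose. The cell cycle genes Ccna2 (-3.87 ± 0.23, adjusted p = 1.18e-05), Ccnb2 (-3.79 ± 0.29, adjusted p = 4.63e-05) and Cenpe (-3.08 ± 0.29, adjusted p = 0.000193) fell. In all, 822 of 23136 genes or transcripts passed, 335 higher and 487 lower, and 796 differed at least 2-fold. The other large rises were those of Cdk5r2 (4.59 ± 0.78, adjusted p = 0.0089), Olfr1505, an olfactory receptor (3.78 ± 0.84, adjusted p = 0.0321), Prg4, lubricin (3.69 ± 0.78, adjusted p = 0.0276, with 2 of 3 Bach2 KO arrays well above background), and Chat, choline acetyltransferase (3.46 ± 0.78, adjusted p = 0.034). Bean1 (at least 2.67-fold, adjusted p = 0.0114) and Adgrg1 (at least 1.43-fold, adjusted p = 0.0142, with 1 of 3 DKO arrays well above background) rose to a bound. Ces2c (-6.06 ± 0.47, adjusted p = 5.54e-05), Ripk4 (-5.47 ± 0.79, adjusted p = 0.00338), Pla2g2d (-5.38 ± 0.41, adjusted p = 4.63e-05), Ppic (-5.33 ± 0.81, adjusted p = 0.00452) and Plet1 (-5.21 ± 0.34, adjusted p = 1.53e-05) fell, Ces2c, Ripk4 and Ppic with 2 of 3 DKO arrays well above background. Slc1a3, a glutamate transporter (at least 81.4-fold), Cracd (at least 73.6-fold), Lilra5, Dysf, dysferlin (at least 31.6-fold), and Lama4, a laminin chain (at least 26.0-fold), fell to a level not well above background on any DKO array. Slc40a1 was at 2.31 without Bach2 KO replicate 3, Ripk4 at -4.42 and Ppic at -4.72 without DKO replicate 1 and Cdk5r2 at 3.57 and Olfr1505 at 2.71 without DKO replicate 3. For Spic, Olfr1505, Prg4 and Chat the highest adjusted p with 1 array left out was 0.0875, 0.125, 0.107 and 0.131, which did not pass.

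Of 49 cell cycle genes, 0 rose, 23 fell and 26 did not pass, or 0 and 38 adjusted over the list alone. As a list they were lower (median -1.77, or -1.50 with members at their bounds, adjusted p = 6.59e-30, and adjusted p = 0.00834 with an estimated correlation). Of 33 alveolar macrophage identity genes, 0 rose, 12 fell and 21 did not pass, or 1 and 16 adjusted over the list alone. Axl (-2.78 ± 0.20, adjusted p = 2.82e-05), Krt79 (-2.95 ± 0.29, adjusted p = 0.000257) and Krt19 (-7.15 ± 0.68, adjusted p = 0.000198) fell, Krt19 with 1 of 3 DKO arrays well above background. The identity list was lower (adjusted p = 2.82e-08, and adjusted p = 0.262 with an estimated correlation). Of 23 PPARgamma target and fatty acid genes, 1 rose, 3 fell and 19 did not pass, or 1 and 5 adjusted over the list alone. Lpl (-2.37 ± 0.27, adjusted p = 0.000738), Pdk4 (-4.97 ± 0.67, adjusted p = 0.00203) and Cidec (-4.27 ± 0.66, adjusted p = 0.00496) fell and Pnpla2 rose (1.28 ± 0.31, adjusted p = 0.0491). Pdk4 and Cidec were well above background on 1 of 3 DKO arrays, and the list was lower (adjusted p = 0.0235, and adjusted p = 0.499 with an estimated correlation). The PPARgamma target and fatty acid genes did not pass with the series matrix values, with the filter on all 12 arrays, without a trend in eBayes, with the 2 groups alone or without both WT replicate 3 and Bach1 KO replicate 3 (highest adjusted p = 0.128). Without Bach2 KO replicate 2 (adjusted p = 0.0653), DKO replicate 1 (adjusted p = 0.0507) or DKO replicate 2 (adjusted p = 0.0559) they did not pass either. Of 25 cholesterol synthesis genes, 0 rose and 0 fell, or 0 and 1 adjusted over the list alone, while the list was lower (adjusted p = 0.011, and adjusted p = 0.44 with an estimated correlation), but cholesterol synthesis genes did not pass with the series matrix values (adjusted p = 0.291). The member past the test within the list was Fdft1 (-1.32 ± 0.33, adjusted p = 0.0527). Of 30 oxidative stress, heme and iron genes, 3 rose, 0 fell and 27 did not pass, or 3 and 2 adjusted over the list alone, and the list did not pass (adjusted p = 0.42). Immediate early and handling stress genes did not pass as a list (3 of 19 rose, 0 fell, or 5 and 0 adjusted over the list alone, adjusted p = 0.274), with Jun among those that rose (2.31 ± 0.40, adjusted p = 0.0103). Krt19 was at -8.21 and Pdk4 at -5.69 without DKO replicate 1 and Cidec at -5.09 without DKO replicate 3. For Pnpla2 and Jun the highest adjusted p with 1 array left out was 0.156 and 0.055, which did not pass.

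Without Bach2 KO replicates 1 and 3 the count of genes was 293 and 347, and without DKO replicates 1, 2 and 3 it was 306, 545 and 418. The share of higher genes was 40.8%, against 20.6% with no scaling, 50.5% with normexp (601 higher and 588 lower), 942 higher and 909 lower with the 2 groups alone and 2013 and 1966 with array quality weights. No scaling moved the median of all genes from 0.03 to -0.22.

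**Figure D5:**
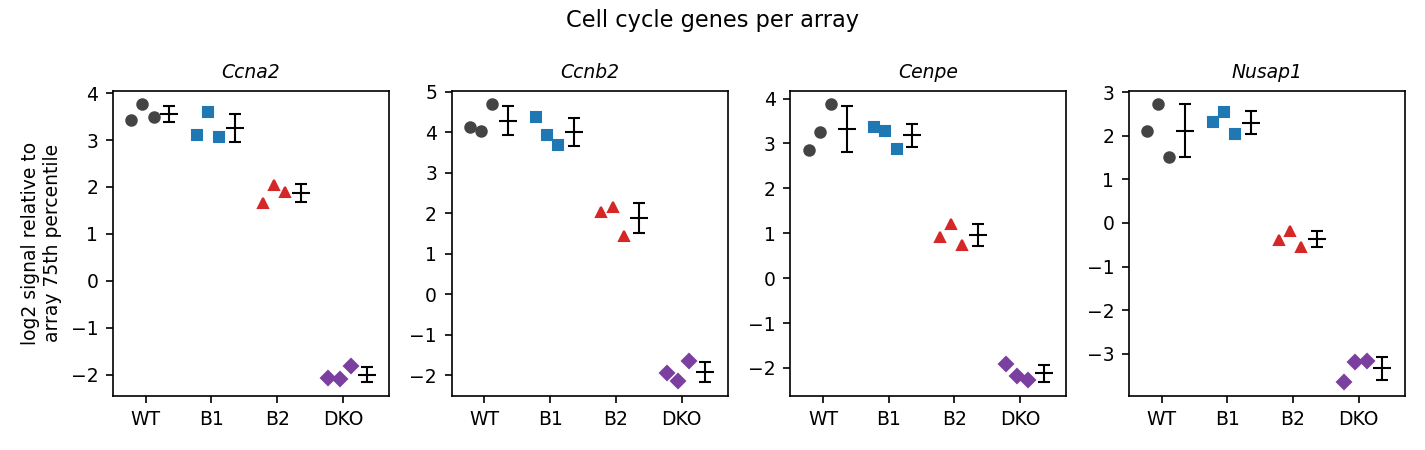
Log2 signal relative to the array's 75th percentile (vertical axis) of 4 cell cycle genes in WT, Bach1 KO (B1), Bach2 KO (B2) and DKO mice (horizontal axis); filled points are arrays well above background, open points are not, and bars give mean ± SD of 3 mice. Ccna2, Ccnb2, Cenpe and Nusap1 lie lowest in DKO.

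Loss of Bach2 where Bach1 was absent was read from DKO against Bach1 KO. The MHC class II genes H2-Aa (5.94 ± 0.51, adjusted p = 6.07e-06), H2-Eb1 (5.68 ± 0.31, adjusted p = 2.26e-07), Cd74 (5.61 ± 0.49, adjusted p = 6.37e-06) and H2-Ab1 (3.95 ± 0.22, adjusted p = 2.52e-07) rose. Arg1, arginase (11.32 ± 1.58, adjusted p = 0.000271), Adam8 (9.65 ± 0.68), F13a1 (9.62 ± 0.55), Car6 (9.28 ± 0.68) and Mmp12 (9.22 ± 0.51, adjusted p = 2.33e-07) rose, all with 2 of 3 Bach1 KO arrays well above background. Rises to a bound were those of Ccl24 (at least 4338-fold, adjusted p = 1.33e-09), Rbp4, a retinol carrier (at least 3763-fold), Ccl7 (at least 3397-fold), Rai14 (at least 1639-fold) and C1qc (at least 997-fold). Fabp1 (-12.40 ± 0.62, adjusted p = 1.15e-07), Perp (-9.74 ± 0.65), Lipf (-9.62 ± 0.28, adjusted p = 7.4e-09), Flvcr2 (-9.33 ± 0.46) and Alox5 (-8.92 ± 0.31) fell, the first 3 with 2 of 3 DKO arrays well above background. Wfdc10 (at least 1251-fold), Spag11b (at least 747-fold), Grb7 (at least 499-fold), Dysf (at least 429.9-fold) and Rufy4 (at least 342-fold) fell to a bound. In all, 6023 of 23133 genes or transcripts passed, 2503 higher and 3520 lower. With no scaling 57.6% of those passing were higher, against 41.6%, and the median of all genes moved from -0.21 to 0.08. H2-Aa was at 5.34, Arg1 at 9.30 and Car6 at 10.29 without Bach1 KO replicate 1, Adam8 at 8.89 without Bach1 KO replicate 3 and Fabp1 at -11.67 and Perp at -8.77 without DKO replicate 3.

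Of 15 MHC class II and antigen presentation genes, 8 rose, 4 fell and 3 did not pass, also when adjusted over the list alone. The MHC list was higher (adjusted p = 0.0149, or 0.168 with an estimated correlation). Alternative activation genes (15 of 21 rose, 0 fell, or 16 and 0 adjusted over the list alone, adjusted p = 8.74e-11, and adjusted p = 0.00147 with an estimated correlation) and chemokine and chemokine receptor genes (16 of 22 rose, 2 fell, or 17 and 2 adjusted over the list alone, adjusted p = 2.17e-09, and adjusted p = 0.00147 with an estimated correlation) were higher. Matrix remodelling genes (13 of 24 rose, 2 fell, or 14 and 2 adjusted over the list alone, adjusted p = 1.85e-07, and adjusted p = 0.00451 with an estimated correlation) and monocyte and recruited macrophage genes (18 of 29 rose, 4 fell, also when adjusted over the list alone, adjusted p = 8.53e-07, and adjusted p = 0.00317 with an estimated correlation) were higher as well. Lower were cell cycle genes (1 of 49 rose, 44 fell, or 1 and 46 adjusted over the list alone, adjusted p = 2.23e-26, and adjusted p = 0.00317 with an estimated correlation) and alveolar macrophage identity genes (3 of 33 rose, 19 fell, or 3 and 20 adjusted over the list alone, adjusted p = 2.93e-08, and adjusted p = 0.0715 with an estimated correlation). PPARgamma target and fatty acid genes were lower too (1 of 23 rose, 10 fell, or 1 and 12 adjusted over the list alone, adjusted p = 0.000371, and adjusted p = 0.112 with an estimated correlation). The T cell marker list was higher (10 of 17 rose, 0 fell, also when adjusted over the list alone, adjusted p = 1.85e-07, and adjusted p = 0.065 with an estimated correlation), as were dendritic cell markers (6 of 12 rose, 1 fell, also when adjusted over the list alone, adjusted p = 0.0212, and adjusted p = 0.112 with an estimated correlation). Inflammatory cytokine and NF-kB genes (10 of 31 rose, 4 fell, also when adjusted over the list alone, adjusted p = 0.0171, and adjusted p = 0.065 with an estimated correlation) and interferon-stimulated genes (9 of 36 rose, 2 fell, also when adjusted over the list alone, adjusted p = 0.0149, and adjusted p = 0.226 with an estimated correlation) were higher. So were unfolded protein response genes (10 of 24 rose, 1 fell, also when adjusted over the list alone, adjusted p = 0.0018, and adjusted p = 0.097 with an estimated correlation). The MHC class II and antigen presentation genes did not pass with the series matrix values (adjusted p = 0.0979). Inflammatory cytokine and NF-kB genes did not pass with the filter on all 12 arrays (adjusted p = 0.0569), T cell markers with the filter on all 12 arrays (adjusted p = 0.139), and dendritic cell markers with the filter on all 12 arrays or without both WT replicate 2 and Bach1 KO replicate 2 (highest adjusted p = 0.256), nor without Bach1 KO replicate 2 (adjusted p = 0.051).

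The interaction, the Bach2 effect without Bach1 minus the Bach2 effect with Bach1, asked whether the effects of the losses added up on the log2 scale. It was positive for the MHC class II genes Cd74 (4.08 ± 0.69, adjusted p = 0.0214), H2-Eb1 (4.05 ± 0.44, adjusted p = 0.00196), H2-Aa (3.78 ± 0.72, adjusted p = 0.0407) and H2-Ab1 (3.43 ± 0.31, adjusted p = 0.000801), which were low in Bach1 KO and not in DKO. It was negative for the cell cycle genes Ccna2 (-3.56 ± 0.33, adjusted p = 0.000801) and Ccnb2 (-3.52 ± 0.41, adjusted p = 0.00273). It was negative as well for Plet1 (-5.05 ± 0.48, adjusted p = 0.000801) and Axl (-2.56 ± 0.28, adjusted p = 0.00196), which were lower in DKO than the sum of the losses. In all, 155 of 23118 genes or transcripts passed, 24 positive and 131 negative, and 3414 had an unadjusted p under 0.05. Other genes with a large interaction were Scarf1 (3.30 ± 0.55, adjusted p = 0.0212), Slc36a2, an amino acid transporter (-7.28 ± 1.24, adjusted p = 0.0233), Igf2bp3 (-6.80 ± 1.06, adjusted p = 0.0146), Ces2c (-5.70 ± 0.67, adjusted p = 0.00273), St14, the protease matriptase (-5.41 ± 0.96, adjusted p = 0.0291), and Awat1 (-5.27 ± 0.85, adjusted p = 0.0177). H2-Aa was at 3.18 without Bach1 KO replicate 1, St14 at -6.33 without Bach1 KO replicate 3, Slc36a2 at -8.62 and Igf2bp3 at -7.61 without WT replicate 2 and Awat1 at -4.56 without WT replicate 3. For Cd74, H2-Aa, Scarf1, Slc36a2, St14 and Awat1 the highest adjusted p with 1 array left out was 0.0653, 0.124, 0.0649, 0.075, 0.0927 and 0.0611, which did not pass.

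Cell cycle genes had 0 positive, 10 negative and 39 not past, or 1 and 23 adjusted over the list alone, and the list was shifted down (adjusted p = 2.11e-20, and adjusted p = 0.0291 with an estimated correlation). Alveolar macrophage identity genes had 0 positive and 6 of 33 negative, or 2 and 12 adjusted over the list alone (adjusted p = 3.94e-06, and adjusted p = 0.249 with an estimated correlation). PPARgamma target and fatty acid genes had 0 positive and 2 of 23 negative, or 1 and 3 adjusted over the list alone (adjusted p = 0.0216, and adjusted p = 0.343 with an estimated correlation). The negative members were Lpl (-2.45 ± 0.38, adjusted p = 0.0146) and Pdk4 (-5.51 ± 0.94, adjusted p = 0.0233). Cholesterol synthesis genes had 0 positive and 0 of 25 negative, also when adjusted over the list alone, and were shifted down (adjusted p = 0.0303, and adjusted p = 0.343 with an estimated correlation). MHC class II and antigen presentation genes had 4 of 15 positive and 0 negative, or 5 and 0 adjusted over the list alone, and the list was shifted up (adjusted p = 0.0357, and adjusted p = 0.343 with an estimated correlation). Its median of 0.03 turned negative with quantile normalization and with no scaling. Oxidative phosphorylation genes had 0 of 32 positive and 0 negative, also when adjusted over the list alone, and were shifted up (adjusted p = 0.0303, and adjusted p = 0.809 with an estimated correlation), with a median that turned negative under quantile normalization. Immediate early and handling stress genes had 1 of 19 positive and 0 negative, or 4 and 0 adjusted over the list alone, with Jun positive (2.98 ± 0.57, adjusted p = 0.0412) and the list shifted up (adjusted p = 0.0397, and adjusted p = 0.249 with an estimated correlation). Pdk4 was at -6.23 without DKO replicate 1. For Lpl, Pdk4 and Jun the highest adjusted p with 1 array left out was 0.0503, 0.079 and 0.123, which did not pass.

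Most of these list calls depended on the settings and on single arrays. PPARgamma target and fatty acid genes did not pass with the filter on all 12 arrays, with limma's fry test or without both WT replicate 3 and Bach1 KO replicate 3 (highest adjusted p = 0.143). Without WT replicate 3 (adjusted p = 0.0581) they did not pass either. The cholesterol synthesis genes did not pass with the series matrix values, with the mean of a gene's probes, with limma's fry test, without both WT replicate 3 and Bach1 KO replicate 3 or without both WT replicate 2 and Bach1 KO replicate 2 (highest adjusted p = 0.58). Without WT replicate 2 (adjusted p = 0.14), Bach1 KO replicate 1 (adjusted p = 0.0568), Bach1 KO replicate 3 (adjusted p = 0.091) or Bach2 KO replicate 1 (adjusted p = 0.0669) they did not pass either. MHC class II and antigen presentation genes did not pass with quantile normalization, with the series matrix values, with normexp on median signals, with array quality weights or without both WT replicate 3 and Bach1 KO replicate 3 (highest adjusted p = 0.246). Without WT replicate 3 (adjusted p = 0.0605), Bach2 KO replicate 2 (adjusted p = 0.124), DKO replicate 1 (adjusted p = 0.0996) or DKO replicate 3 (adjusted p = 0.0735) they did not pass either. The oxidative phosphorylation genes did not pass with quantile normalization, with no scaling, with the series matrix values, with normexp on median signals, with limma's fry test or without both WT replicate 2 and Bach1 KO replicate 2 (highest adjusted p = 0.477). Without WT replicate 1 (adjusted p = 0.106), Bach1 KO replicate 2 (adjusted p = 0.304) or DKO replicate 3 (adjusted p = 0.28) they did not pass either. The immediate early and handling stress genes did not pass with quantile normalization, with no scaling, with the series matrix values, with normexp on median signals, with the filter on all 12 arrays, with every probe on its own, with array quality weights or without both WT replicate 2 and Bach1 KO replicate 2 (highest adjusted p = 0.24). Without WT replicate 2 (adjusted p = 0.175), Bach1 KO replicate 1 (adjusted p = 0.0636), Bach2 KO replicate 2 (adjusted p = 0.124), DKO replicate 2 (adjusted p = 0.0551) or DKO replicate 3 (adjusted p = 0.0531) they did not pass either.

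Without WT replicates 1 and 2 the count of interaction genes was 77 and 265, without Bach2 KO replicates 1 and 2 it was 75 and 86, without DKO replicate 1 it was 86, and without both WT replicate 3 and Bach1 KO replicate 3 it was 241. The share of positive genes was 15.5%, against 3.09% with no scaling, 27.9% with the series matrix values and 36.4% with normexp, and the median of all genes was 0.09, or -0.32 with no scaling.

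The Bach2 effect was compared between mice with Bach1 (Bach2 KO against WT) and without it (DKO against Bach1 KO), which share no array. Of the genes that passed in each, 4109 did so in the same direction (1638 up and 2471 down) and 23 in opposite directions, where independent lists would share 310.4 up and 868 down. Across 23118 genes, which are not independent replicates, the log2 differences correlated at r = 0.796 with a covariance of 2.34. In 100 simulated draws without an effect the mean covariance was 0.00303, r lay between -0.669 and 0.719, and 0 genes were shared. Draws without an effect leave few genes to pass, so this count of 0 says nothing about the overlap. Bach2 KO and DKO against WT, which share the WT arrays, had 4728 genes in the same direction and 8 in opposite directions, where independent lists would share 303 up and 947 down. There r was 0.871 and the covariance 2.58, against a simulated 0.178. The 3 WT arrays were too few to split, so part of that excess may come from the shared arrays. Bach1 KO against WT, which shares the WT arrays with the next comparisons, shared 3 genes in the same direction and 7 in opposite directions with Bach2 KO against WT (independent lists 2.96 and 2.23). There r was 0.213 and the covariance 0.243, against a simulated mean r of 0.508 and covariance of 0.175. It shared 4 and 8 with DKO against WT (independent lists 2.08 and 1.72), where r was 0.212 and the covariance 0.241, against a simulated 0.514 and 0.177. The simulated draws shared 0 genes in both. With DKO against Bach2 KO, which shares no array with it, it shared 2 genes in the same direction and 0 in opposite directions (independent lists 0.268 and 0.229). There r was -0.00186 and the covariance -0.00108, against a simulated mean r of 0.0105 and covariance of 0.00199.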

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

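The tests of carried-over cells, of slide and scan day and of slide row for H2-Aa and Cd74 were chosen after the results were seen. The interaction test, which asked whether the Bach2 effect differs between mice with and without Bach1, marked the genes and lists of the next paragraph.

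In all, 155 genes or transcripts differed. Those named were Cd74 (4.08), H2-Eb1 (4.05), H2-Aa (3.78), H2-Ab1 (3.43) and Scarf1 (3.3) with a positive log2 difference between the effects, and Slc36a2 (-7.28), Igf2bp3 (-6.8), Ces2c (-5.7), St14 (-5.41) and Awat1 (-5.27) with a negative one. The lists that differed had an adjusted p of 3.94e-06 (alveolar macrophage identity), 0.0216 (PPARgamma targets), 0.0303 (cholesterol synthesis), 0.0357 (MHC class II), 2.11e-20 (cell cycle), 0.0303 (oxidative phosphorylation) and 0.0397 (immediate early). With an estimated correlation the adjusted p was 0.0291 for cell cycle, which passed, and did not pass for the others, at 0.249 for identity and immediate early, 0.343 for PPARgamma targets, cholesterol synthesis and MHC class II, and 0.809 for oxidative phosphorylation. Splits of all 12 arrays into 4 groups of 3 mix arrays with and without Bach2, so the Bach2 effect enters their spread and they decide nothing about chance. Of 100 such splits, 2 gave 155 genes or more, the real one included, with 9697 as the highest other. The Bach2 effect can enter a count that large, so it does not show a further structure of the samples. For lists, 47 splits gave 7 or more, with 15 as the highest other.

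With 3 against 3 arrays the 10 splits are too few for a share under 0.05. All but the real one mix genotypes, so a large genotype effect enters the spread and a 0 decides nothing. The real count of genes and the highest other were 14 and 99 for Bach1 KO against WT (4 of 10 as large). For Bach2 KO and DKO against WT they were 8571 and 6285 against 0 (1 of 10). For DKO against Bach2 KO and Bach1 KO they were 822 and 6023 against 0 (1 of 10). The Bach1 KO and WT splits with 99, 58, 62 and 5 genes put WT replicate 2 and Bach1 KO replicate 2 on one side, and the others beside the real one gave 0. This points to a structure of the samples in which these arrays go together. For lists these were 3 and 4 (2 of 10), 13 and 11 (1 of 10), 14 and 13 (1 of 10), 4 and 7 (7 of 10), and 13 and 11 (1 of 10).

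MHC class II genes were lower in Bach1 KO than in WT, with a median of -3.92 over H2-Aa, H2-Ab1, H2-Eb1 and Cd74. Fewer dendritic cells carried over would lower their other markers alike. The median of 5 such markers was 0.0117 (SD 0.947, lowest -2.11), which argues against this as the only cause. With slide row as a term, the larger adjusted p of H2-Ab1 (-3.68) and H2-Eb1 (-4.79) was 0.0178, while H2-Aa went from -4.20 ± 0.51 to -5.40 ± 0.57 (adjusted p = 0.0569) and Cd74 from -3.80 ± 0.49 to -4.52 ± 0.64 (adjusted p = 0.0981). That test asked for calls that hold, but by the design it leaves the difference to the 1 Bach1 KO array in the slide row of the 3 WT arrays, and 1 array excludes nothing, so slide row and genotype cannot be told apart for these genes. Loss of Bach1 stays open and was not tested beyond the genotypes: where Bach2 was absent too, in DKO against Bach2 KO, the list of MHC class II and antigen presentation genes did not pass (adjusted p = 0.648).

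Cell cycle genes were lower in DKO than in Bach2 KO. Array scaling is argued against by the list's median, -2.02 to -1.17 over the scalings. Camera's highest adjusted p over 4 other scalings, 9.79e-27, decides nothing where scaling moves all genes alike. Loss of dim signals is argued against by 10000 random lists of the same brightness, whose lowest median was -0.42 against the list's -1.77 (-1.50 with members at their bounds). The DKO slide and scan day, shared by 0 arrays of other genotypes, cannot be told apart from loss of Bach1 on top of Bach2. Each could be the cause.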

How the results depend on the processing

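Normexp on median signals, slide row and leaving out the WT and Bach1 KO arrays with number 3, or those with number 2, together were chosen after results were seen, and the cause of the changes was not tested. Normexp on mean signals was not run, because the files hold no mean signal; comparisons within slide 1 exist for 2 comparisons, and the interaction has no fit on the 2 groups alone. Genes changed in Bach1 KO against WT (14) became 27 with quantile normalization, 7 with the filter on all 12 arrays, 188 with array quality weights, 2 with the 2 groups alone, 4 within slide 1, 6 at an adjusted p under 0.01, 5 with slide row, 29 without both arrays with number 3 and 158 without both with number 2. Its 3 lists became 8 without a filter, 1 under 0.01, 0 with an estimated correlation (limma camera), 6 with normexp and 1 with slide row. Genes in Bach2 KO against WT (8571) became 4929 within slide 1, 4786 under 0.01 and 519 with slide row, and its 13 lists 6 with an estimated correlation. In DKO against WT, 6285 genes became 10708 with weights and 3486 under 0.01, and 14 lists became 6 with an estimated correlation. In DKO against Bach2 KO, 822 genes became 1348 with quantile normalization, 1451 with the series matrix, 3979 with weights, 1851 with the 2 groups alone, 243 under 0.01 and 1369 without both arrays with number 3, and 4 lists became 2 with the series matrix, 2 under 0.01 and 1 with an estimated correlation. In DKO against Bach1 KO, 6023 genes became 9089 with weights and 3320 under 0.01, and 13 lists became 5 with an estimated correlation and 20 with fry. The 155 interaction genes became 90 with the filter on all 12 arrays, 1395 with weights, 49 under 0.01 and 241 without both arrays with number 3, and its 7 lists 4 with quantile normalization, 3 with the series matrix, 2 under 0.01, 1 with an estimated correlation, 4 with normexp and 4 without both arrays with number 2. The overlap of 4109 genes became 6350 with weights and 2288 under 0.01. Lum in Bach2 KO against WT turned to -0.05 with normexp. Leaving out each array in turn gave 7 to 86, 5979 to 9495, 4353 to 7314, 293 to 1059, 4170 to 6834 and 75 to 265 genes for the 6 comparisons in the order above, 2 to 6, 12 to 14, 13 to 14, 3 to 6, 13 to 15 and 4 to 9 lists, -1.53 to -1.25 for Bach1 in Bach1 KO against WT and 3087 to 4488 for the overlap. Of 5260 values of named genes over the other alternatives, 5092 kept their direction and side of the threshold, 153 fell below it, 14 came past it and 1 turned, and slide row gave 40 of the falls among its 105 values; leaving out an array gave 3120, of which 2993 kept them, 122 fell below and 5 came past.

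With a replicate block, 10, 8523, 6223, 741, 5985 and 128 genes and 3, 13, 14, 4, 13 and 7 lists passed, Bach1 was at -1.43 and the overlap was 4097. The numbers do not pair the mice: the 18 pairs of arrays with the same number correlated at -0.152 to 0.383 after genotype was removed, and 5 of 12 arrays had their best partner under their own number.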

Other observations

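The test of carried-over T cells was chosen after the result was seen. The genes named in this part were picked after their values were seen and carry no test beyond those named.

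The glycolysis and hypoxia list did not pass in Bach2 KO against WT, but single members did. Of the glycolysis and hypoxia genes, Pfkl (1.72 ± 0.26, adjusted p = 0.000457) and Slc2a1 (1.86 ± 0.33, adjusted p = 0.00152) rose and Pdk1 (-1.79 ± 0.27, adjusted p = 0.000482) and Car9 (-1.68 ± 0.24, adjusted p = 0.000301) fell.

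Spic had a mean of -3.21 in WT and -2.48 in Bach2 KO, against 2.34 in Bach1 KO and 2.25 in DKO, the genotypes without Bach1. The difference of Bach1 KO against WT did not pass (5.54 ± 0.95, adjusted p = 0.0773), with 2 of 3 WT arrays well above background.

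T cell markers were higher in Bach2 KO than in WT, as given above. Slide is argued against by the adjusted p of 2.18e-07 within slide 1, while over all alternatives the highest was 0.336 with the filter on all 12 arrays. The 5 members well above background on all arrays that did not rise (median -0.33) were picked by outcome, so this value decides nothing. Carried-over T cells and expression in the macrophages themselves cannot be told apart.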
